A study of Mus musculus with 16 samples.

How the data were processed

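Gene expression was measured in calvaria, the flat bones of the skull roof, from 16 male mice taken at postnatal day 7. The mice fell into 4 genotypes with 4 mice each, written here as the labels abbreviate them. WT mice were wild type, R-Het mice lacked 1 copy of Runx2, A-KO mice lacked both copies of Axin2, and A-KO:R-Het mice carried both defects. Axin2 is a feedback inhibitor of Wnt signalling, and Runx2 is a transcription factor that osteoblasts require. Per the labels' protocols, RNA was extracted with TRIzol, and 200 ng of total RNA was converted to biotinylated cRNA for single-colour Illumina bead arrays. Per the labels, the arrays lay on 2 chips of 8, and each chip held 2 arrays of every genotype. The label of A-KO replicate 2 calls that array damaged and excluded, so 15 arrays were compared, with 4 WT, 4 R-Het, 3 A-KO and 4 A-KO:R-Het arrays. Groups came from the genotype label of each sample. The labels give no replicate numbers, so replicates were numbered in the order of their records and were not paired across genotypes.

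The values used were the authors' deposited, already normalized probe intensity values on a linear scale. How the authors corrected background and normalized between arrays is not given in the sources used here, and no background floor is stated. The median intensity of the 15 arrays lay between 92.9 and 95.5, so the arrays had been brought to a common level. A second table of scanner signals and detection p-values was not used here. Its 32 columns carry running numbers that match no sample label, so none could be assigned to a mouse. The fit first planned was to start from those scanner signals with normal-exponential background correction and quantile normalization. It was replaced by log2 of the deposited values, and the planned detection filter by a filter on rank within the array. Everything else in the design, including the comparisons, the gene lists, the rule for named genes and most alternatives, was fixed before the data were examined and was kept.

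Of 25697 probes, 23978 were paired with 1 gene symbol by the platform annotation, 0 with several and 1719 with none. The annotation's Entrez identifiers matched the mouse RefSeq gene table of assembly GRCm38.p6 for 23962 probes, and 0 symbols needed updating. That table was used for names and for which genes neighbour each other, and no coordinates were taken from it. A probe was kept when it lay above the median of its array on at least 3 of the 15 arrays, which left 14212 probes, 13381 of them named. Where several probes of a gene remained, as for 2505 genes, the probe with the highest mean was taken, which gave 9918 genes for testing. Runx2 is not analysed here. Axin2 was measured by 1 probe, and its place relative to the deleted part of the gene is not given in the sources used here, so its level checks no label.

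A linear model with 1 mean per genotype was fitted to log2 intensity over all 15 arrays in limma 3.58.1 under R 4.3.3, and moderated with its empirical Bayes step. All genotypes shared 1 estimate of the spread for each gene. The comparisons were A-KO against WT, R-Het against WT, A-KO:R-Het against WT, against A-KO and against R-Het, the interaction, and the averaged effects of Axin2 loss and of Runx2 allele loss. The interaction is the effect of Axin2 loss in Runx2 heterozygous mice minus that in Runx2 wild-type mice. P-values were adjusted over all tested genes by the Benjamini-Hochberg method, with a threshold of 0.05. Changes are given as log2 fold change ± standard error. The 3 comparisons against WT share the WT arrays, so their gene sets are not independent, and no overlap between them was tested. Each array came from its own mouse, and the number of arrays limits the precision.

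Gene lists for 34 pathways and cell types were fixed beforehand, and 33 of them had at least 4 measured members. The lists covered osteoblast and bone matrix, osteocyte, Wnt targets and feedback inhibitors, Wnt ligands, receptors and antagonists, the beta-catenin destruction complex, FGF, BMP and TGF-beta, and hedgehog signalling. They also covered craniosynostosis and suture genes, osteoclast, cartilage, fibrous matrix and periosteum, proteoglycan chain synthesis, matrix metalloproteinases, cell cycle and adipocyte genes. Markers of other cells were erythroid, neutrophil, macrophage, B cell, T and NK cell, mast cell, endothelium, smooth muscle, skeletal muscle, brain and nerve, skin and hair, and meninges. Lists of interferon response, immediate early and handling stress, hypoxia and glycolysis, unfolded protein response, mitochondrial respiration and ribosomal protein genes completed the set. Each list was tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over the 33 lists. The test was repeated with an estimated correlation between members and with limma's fry, which asks whether a list's genes move 1 way without comparing them with other genes. All 87 calls with the preset correlation had a median and a mean change with the sign of the test.

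The genes named per comparison followed a rule. It took Axin2, the 10 largest rises and 10 largest falls among genes past the threshold whose arrays did not overlap between the 2 genotypes, and up to 4 members past the threshold from each list. The overlap condition was dropped for the averaged effects and the interaction. Where fewer than 5 genes passed, the 5 smallest p-values were taken and given as values. A list that was called without any member past the threshold contributed its 3 members with the smallest p, again as values.

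The calculations were tested on simulated data, with 67, 67 and 66 of the 9918 genes shifted by 1.5-fold, 2-fold and 3-fold. For A-KO against WT, 70.1%, 91% and 98.5% of these were recovered, and 5 unchanged genes were called. For A-KO:R-Het against WT the shares were 82.1%, 94% and 100%, with 10 unchanged genes called. For the averaged Runx2 effect they were 89.6%, 98.5% and 97%, with 14. A shifted list was called in each of the 3 simulations, with 0, 0 and 1 other lists in that order. Genes were drawn independently, so wrong list calls where members vary together were not assessed. Real A-KO against WT had fewer calls, 31, so its adjustment was stricter and its recovery may be lower.

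Alternatives tried for each count were another background correction, quantile normalization, no filter, every probe on its own, chip as a fixed or random block, each chip alone, the damaged array kept in, array weights, a variance trend with robust moderation, a threshold of 0.1, and each array left out in turn. The compared genotypes alone were fitted for the 5 comparisons of a pair of genotypes. Cyclic loess, scaling to a common median, a stricter filter, the skeletal muscle list mean as a covariate, and leaving out the 3 arrays highest in skeletal muscle genes were added after seeing the data.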

Results

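Expression of 9918 genes was compared in calvaria of postnatal day 7 male mice of 4 genotypes. The 15 arrays used comprised 4 from wild-type mice (WT), 4 from mice with 1 functional Runx2 allele (R-Het), 3 from mice without Axin2 (A-KO) and 4 from mice with both defects (A-KO:R-Het). The design asked how loss of Axin2, a feedback inhibitor of Wnt signalling, changes gene expression in the skull vault, how loss of 1 allele of Runx2, a transcription factor required by osteoblasts, changes it, and how both act together. Median intensity lay between 92.9 and 95.5 on the 15 arrays, and the highest intensity on an array was between 22340 and 28330. The array labelled as damaged had a maximum of 80920 and a mean correlation of 0.949 with the other arrays.

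Arrays of 1 genotype resembled each other little more than arrays of different genotypes. The median correlation across genes was 0.988 within genotypes and 0.986 between them, and genes are not independent replicates. The first principal component held 27% of the variance, and 16 of its 50 leading genes belonged to the 18 measured genes of the skeletal muscle list, such as Acta1 and Myl1. The mean of this list varied within every genotype, with an SD of 1.34 in WT, 1.92 in R-Het, 1.04 in A-KO and 1.25 in A-KO:R-Het (log2, n = 4, 4, 3 and 4). WT replicates 1 and 3 and R-Het replicate 4 were highest, at 1.62, 2.27 and 2.27. The first principal component thus followed skeletal muscle genes. The second held 16.2%, with scores of 0.35 to 10.05 on the arrays with Axin2 and -16.09 to -5.88 on those without it, except A-KO:R-Het replicate 1 at 11.9.

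The Axin2 probe read 7.67 ± 0.20 in WT, 7.97 ± 0.09 in R-Het, 7.48 ± 0.20 in A-KO and 7.49 ± 0.17 in A-KO:R-Het (log2 intensity, mean ± SD, n = 4, 4, 3 and 4). The difference between A-KO and WT was -0.19 ± 0.12 (log2 fold change ± standard error, as for all changes given here, limma adjusted p = 0.549). The place of this probe relative to the deleted part of the gene is not known, so its level checks neither the labels nor the knockout. Runx2 is not analysed here, so the labels of the groups with 1 Runx2 allele were not checked from expression either.

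**Figure D1:**
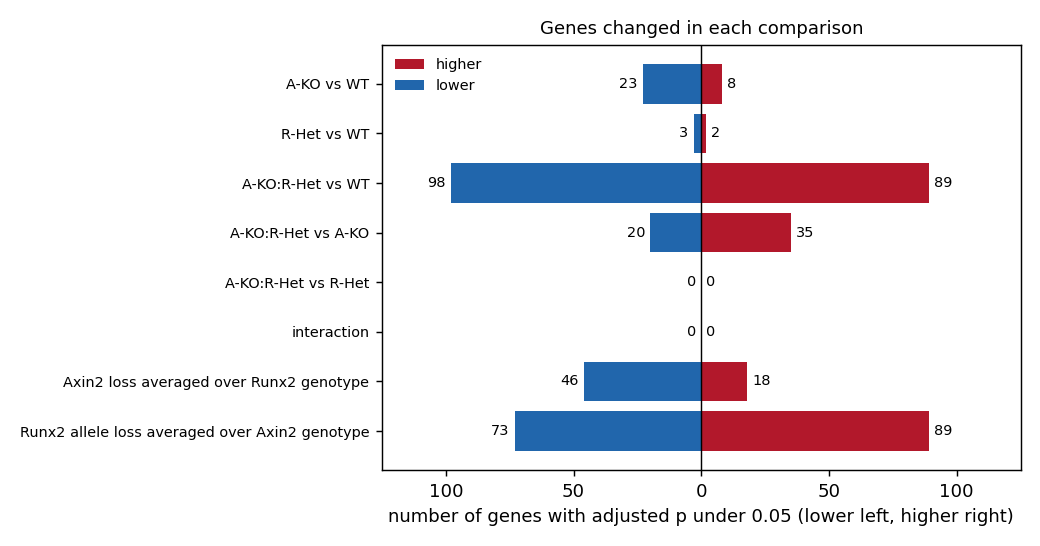
Horizontal bars give the number of genes past an adjusted p of 0.05 in each of the 8 comparisons, with genes lower to the left of 0 and genes higher to the right. The 187 genes of A-KO:R-Het against WT were the most, and A-KO:R-Het against R-Het and the interaction had 0.

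In calvaria without Axin2, B lymphocyte genes were lower as a group and gave the smallest p of the lists tested (camera adjusted p = 2.56e-08, adjusted p = 0.377 with an estimated correlation). Vpreb1, which encodes part of the surrogate light chain of immature B cells, was 3.17-fold lower in A-KO than in WT (-1.67 ± 0.20, adjusted p = 0.00125, n = 3 and 4). Mzb1, a chaperone of immunoglobulin-secreting cells, was 2.43-fold lower (-1.28 ± 0.14, adjusted p = 0.00112), and Pou2af1, a B cell transcriptional coactivator, was 1.99-fold lower (-0.99 ± 0.16, adjusted p = 0.0149). In total 31 genes changed, 8 higher and 23 lower, and 1257 genes had an unadjusted p under 0.05. In all 31, the A-KO and WT arrays did not overlap, against 1383 such genes among all 9918 and 5.71% by chance.

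Of the 8 measured members of the B cell list, 4 fell (Vpreb1, Vpreb3, Cd79a and Cd79b), and 5 fell when adjusted over the list alone. The list's median change was -0.61 (camera adjusted p = 2.56e-08, adjusted p = 0.377 with an estimated correlation). Genes of other blood cells moved the same way as groups. The neutrophil list of 14 genes had a median of -0.86 (adjusted p = 9.09e-08, adjusted p = 0.432 with an estimated correlation), with 0 members past the threshold over all genes and 3 adjusted over the list alone. The erythroid list of 9 genes had a median of -0.70 (adjusted p = 1.51e-05, adjusted p = 0.432 with an estimated correlation), with 0 and 6 members. Slc4a1, the erythrocyte anion exchanger, stood at -2.48 ± 0.68 (adjusted p = 0.127), and Mpo, a neutrophil granule enzyme, at -1.47 ± 0.47 (adjusted p = 0.185). The mast cell list, at a median of -0.72 (adjusted p = 0.000441, adjusted p = 0.432 with an estimated correlation), and the macrophage list, at -0.17 (adjusted p = 0.00118, adjusted p = 0.432 with an estimated correlation), were lower too. Cxcl12, a chemokine that retains haematopoietic cells in marrow, fell by 0.86 ± 0.10 (adjusted p = 0.00125), and Esr1, the estrogen receptor alpha gene, fell by 0.83 ± 0.15 (adjusted p = 0.0309). Cytip and Dner fell by 1.06 ± 0.21 and 0.94 ± 0.19 (adjusted p = 0.0489 for both).

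The 8 genes that rose in A-KO did so by 1.42-fold to 1.66-fold. Abca5, a membrane transporter of the ATP-binding cassette family, rose most (0.73 ± 0.09, adjusted p = 0.00125), followed by Tnfrsf22, Dnajc17 and Ccnd1. Ccnd1, the cyclin D1 gene and a Wnt target, rose by 0.59 ± 0.11 (adjusted p = 0.0434) and was the single member past the threshold among 12 measured Wnt targets and feedback inhibitors (2 when adjusted over the list alone). As a group these targets were higher, with a median of 0.17 (adjusted p = 0.0069, adjusted p = 0.377 with an estimated correlation). Lss, which makes lanosterol, rose by 0.53 ± 0.11, and Agpat2, an enzyme of phospholipid synthesis, by 0.50 ± 0.09 (adjusted p = 0.0489 and 0.0372). Avil and Ddost rose by 0.56 ± 0.10 and 0.52 ± 0.10. The cell cycle list of 21 genes was higher, at a median of 0.24 (adjusted p = 0.000373, adjusted p = 0.562 with an estimated correlation), with 0 members past the threshold.

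Further lists were lower in A-KO. These were cartilage, at a median of -0.24 (adjusted p = 0.00187, adjusted p = 0.581 with an estimated correlation), and immediate early and handling stress genes, at -0.42 (adjusted p = 0.000441, adjusted p = 0.523 with an estimated correlation). Interferon response genes stood at -0.30 (adjusted p = 0.0286, adjusted p = 0.581 with an estimated correlation) and skeletal muscle genes at -1.03 (adjusted p = 0.00457, adjusted p = 0.645 with an estimated correlation). The skeletal muscle median was 0.33 on chip 1 and -1.65 on chip 2. The other 10 of the 11 called lists had the same sign on both chips, and the B cell median was -0.67 and -0.60. With chip as a block 28 genes changed, and chip 1 alone, with 1 A-KO array, and chip 2 alone, with 2, each gave 0. The count of 31 was 0 with the damaged array kept in and 6 without the 3 arrays highest in skeletal muscle genes. It also rested on single arrays: it was 9, 19 and 15 without WT replicates 1, 2 and 3, 4, 11 and 10 without A-KO replicates 1, 3 and 4, and 16 without A-KO:R-Het replicate 3 or 4, while 61, 69 and 76 genes changed without WT replicate 4, R-Het replicate 4 and A-KO:R-Het replicate 1. With 1 array left out, medians ran widely or calls were lost for Wnt targets (0.09 to 0.22), cartilage (-0.36 to -0.21), macrophage (-0.20 to -0.10), skeletal muscle (-1.55 to -0.38, lost in 2), interferon response (-0.61 to -0.07, lost in 3) and immediate early (-0.63 to -0.11, lost in 1). Other settings that ended list calls or moved medians over 1.5 times gave, with the damaged array kept, Wnt targets (0.09, adjusted p = 0.0679), neutrophil (-0.21, adjusted p = 0.0662), mast cell (-0.46) and skeletal muscle (-0.36, adjusted p = 0.0847). With the muscle covariate the values were skeletal muscle (0.08, adjusted p = 0.782) and interferon response (-0.27, adjusted p = 0.0529). Leaving out the 3 arrays highest in muscle genes gave cartilage (-0.47), skeletal muscle (0.19, adjusted p = 0.872) and interferon response (-0.54).

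Loss of 1 Runx2 allele on its own changed few single genes but moved skeletal cell groups. In total 5 genes changed, 2 higher and 3 lower in R-Het than in WT (n = 4 each), with 916 genes at an unadjusted p under 0.05. Aard rose 1.90-fold (0.93 ± 0.14, adjusted p = 0.0396), and Six2, a homeobox gene of the suture list, rose 1.42-fold (0.51 ± 0.09, adjusted p = 0.0421). Cldn10, a tight junction gene, fell by 0.91 ± 0.14 (adjusted p = 0.0396), Manba, a lysosomal mannosidase, fell by 0.53 ± 0.09 (adjusted p = 0.0421), and Tmem86a fell by 0.46 ± 0.07 (adjusted p = 0.0396). For all 5 the arrays of both genotypes did not overlap, against 500 such genes in all and 2.86% by chance.

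Fibrous matrix and periosteum genes were higher in R-Het, with a median of 0.25 over 20 genes (adjusted p = 1.44e-09, adjusted p = 0.00448 with an estimated correlation). None of them passed over all genes, at 0 members, but 9 did when adjusted over the list alone. Fmod, a collagen-binding proteoglycan, stood at 0.47 ± 0.10 and Thbs2 at 0.33 ± 0.08 (adjusted p = 0.107 and 0.139). Osteoclast genes were lower, with a median of -0.29 over 13 genes (adjusted p = 2.65e-06, adjusted p = 0.0495 with an estimated correlation), with 0 members past the threshold and 6 adjusted over the list alone. Tcirg1, a subunit of the osteoclast proton pump, stood at -0.47 ± 0.09, and Dcstamp and Oscar, both needed for osteoclast formation, at -0.63 ± 0.13 each (adjusted p = 0.0655, 0.107 and 0.107). Cartilage genes were higher, with a median of 0.54 over 15 genes (adjusted p = 1.73e-08, adjusted p = 0.297 with an estimated correlation) and 2 members adjusted over the list alone. Epyc, a small cartilage proteoglycan, stood at 0.88 ± 0.19 and Matn4, a cartilage matrix protein, at 0.47 ± 0.12 (adjusted p = 0.107 and 0.15).

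Smaller shifts were seen in R-Het for Wnt ligands, receptors and antagonists (median 0.06, adjusted p = 0.0112, adjusted p = 0.297 with an estimated correlation) and craniosynostosis and suture genes (0.07, adjusted p = 0.0342, adjusted p = 0.568 with an estimated correlation). Unfolded protein response genes were higher (0.16, adjusted p = 0.00905, adjusted p = 0.379 with an estimated correlation), as were immediate early and handling stress genes (0.21, adjusted p = 0.0327, adjusted p = 0.584 with an estimated correlation). Mitochondrial respiration genes were lower (-0.18, adjusted p = 0.00159, adjusted p = 0.584 with an estimated correlation), as were endothelial genes (-0.17, adjusted p = 0.00433, adjusted p = 0.57 with an estimated correlation). Skeletal muscle genes were lower beside them, with a median of -1.40 (adjusted p = 0.000261, adjusted p = 0.584 with an estimated correlation). All 10 called lists had the same sign on both chips: the fibrous median was 0.23 and 0.27, the osteoclast median -0.30 and -0.25, and the cartilage median 0.41 and 0.60. With chip as a block 9 genes changed, and each chip alone gave 0. The count of 5 was 1 with the skeletal muscle covariate and 1 without the 3 arrays highest in muscle genes; it was 0 without WT replicate 1 or 4, R-Het replicate 1, 2 or 3, A-KO replicate 3 or 4 or A-KO:R-Het replicate 2 or 4, 1 without WT replicate 2 or A-KO:R-Het replicate 3, 2 without A-KO replicate 1, and 15 without R-Het replicate 4. The 10 called lists were 6 with the muscle covariate, 5 without R-Het replicate 1 and 4 without WT replicate 3. Leaving out single arrays moved these medians over 1.5 times or ended their calls: Wnt ligands and receptors (0.05 to 0.11, lost in 2), suture (0.04 to 0.12, lost in 6), osteoclast (-0.42 to -0.19), endothelium (-0.29 to -0.11, lost in 2), skeletal muscle (-2.35 to -0.71, lost in 2), immediate early (0.14 to 0.28, lost in 4), unfolded protein response (0.11 to 0.20, lost in 1) and mitochondrial respiration (-0.32 to -0.11, lost in 2). List medians that lost their call or moved over 1.5 times in other settings were, with the damaged array kept, immediate early (0.20, adjusted p = 0.132). With the muscle covariate these were suture (0.03, adjusted p = 0.242), skeletal muscle (0.05, adjusted p = 0.925), immediate early (0.15, adjusted p = 0.25), unfolded protein response (0.14, adjusted p = 0.0629) and mitochondrial respiration (-0.09, adjusted p = 0.242). Without the 3 arrays highest in muscle genes these were cartilage (0.30), endothelium (-0.29) and immediate early (0.28, adjusted p = 0.0768).

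**Figure D2:**
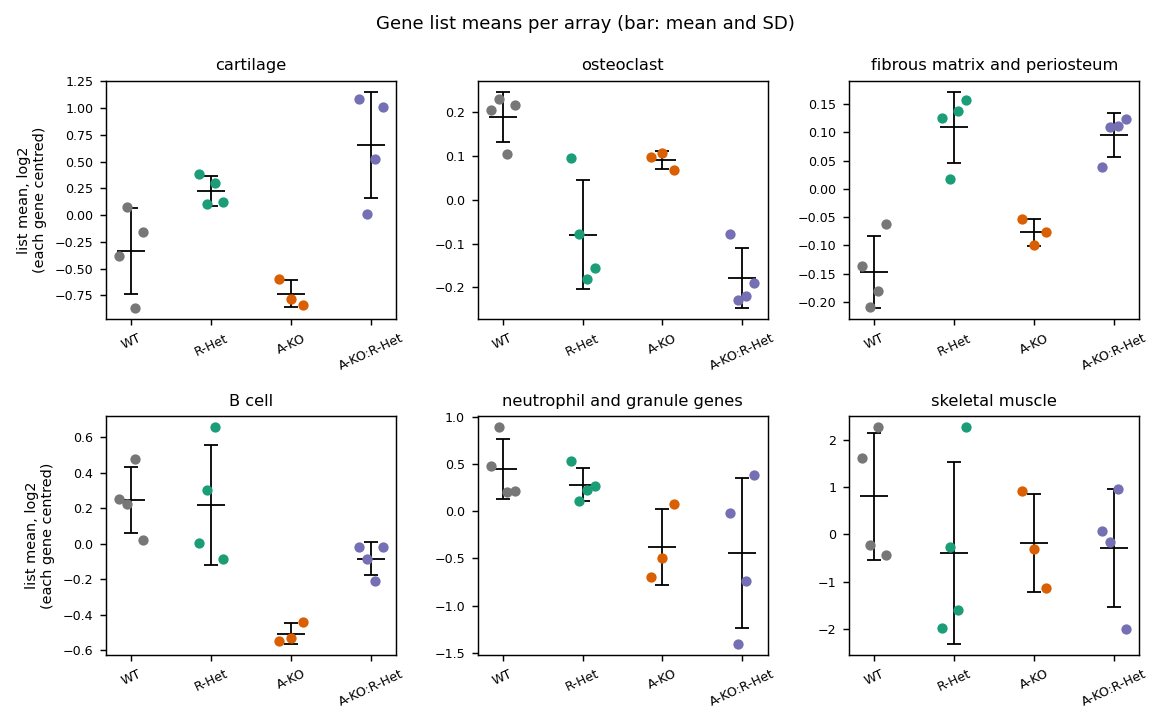
Points give the mean of each gene list on each of the 15 arrays (log2, each gene centred on its mean), by genotype, with bars for the group mean and SD. Cartilage means were highest in A-KO:R-Het, osteoclast means were lower in both groups with 1 Runx2 allele, and skeletal muscle means spread widely within every genotype.

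Cartilage genes were higher as a group in A-KO:R-Het than in WT, with a median of 1.02 over 15 genes (camera adjusted p = 3.02e-15, adjusted p = 0.0841 with an estimated correlation). Epyc rose 2.50-fold (1.32 ± 0.19, adjusted p = 0.00597, n = 4 each) and Sox5, a transcription factor of chondrocytes, rose 2.03-fold (1.02 ± 0.17, adjusted p = 0.00795). Osteoclast genes were lower, led by Oscar, 1.76-fold lower (-0.82 ± 0.13, adjusted p = 0.00772), and Dcstamp, 1.71-fold lower (-0.78 ± 0.13, adjusted p = 0.00795). In total 187 genes changed in these mice with both defects, 89 higher and 98 lower, and 1362 had an unadjusted p under 0.05. Arrays of both genotypes did not overlap for 181 of the 187, against 849 genes in all and 2.86% by chance.

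Among cartilage members, 4 rose (Epyc, Sox5, Matn4 and Cytl1) and 13 did when adjusted over the list alone. Mia and Scrg1, 2 further genes of chondrocytes, rose by 1.31 ± 0.24 and 1.05 ± 0.20 (adjusted p = 0.0115 and 0.0155). The osteoclast list had a median of -0.34 (adjusted p = 3.38e-08, adjusted p = 0.0268 with an estimated correlation), and 4 of its 13 genes fell, 6 adjusted over the list alone. Besides Oscar and Dcstamp these were Acp5, the tartrate-resistant acid phosphatase, at -0.68 ± 0.12 (adjusted p = 0.0109), and Tcirg1 at -0.48 ± 0.09 (adjusted p = 0.00968). The fibrous matrix list had a median of 0.24 (adjusted p = 1.39e-05, adjusted p = 0.0268 with an estimated correlation); Fmod and Thbs2 rose by 0.61 ± 0.10 and 0.41 ± 0.08 (adjusted p = 0.00795 and 0.0154), the 2 members past the threshold, and 6 passed adjusted over the list alone.

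Of 27 Wnt ligands, receptors and antagonists, 3 rose, namely Wnt10a (0.67 ± 0.13), Dkk3 (0.57 ± 0.11) and Ror2 (0.48 ± 0.11), with adjusted p of 0.0162, 0.0155 and 0.033. Adjusted over the list alone 7 rose and 1 fell, and the list's median was 0.10 (adjusted p = 0.00264, adjusted p = 0.135 with an estimated correlation). Hhip, which binds and restrains hedgehog ligands, rose by 0.68 ± 0.12 (adjusted p = 0.00968), and Bmp3, a bone morphogenetic protein antagonist made by bone cells, fell by 0.43 ± 0.10 (adjusted p = 0.0425). Zic1 (0.71 ± 0.13, adjusted p = 0.0129) and Six2 (0.36 ± 0.09, adjusted p = 0.0427) rose among 16 craniosynostosis and suture genes, whose median was 0.17 (adjusted p = 0.00729, adjusted p = 0.246 with an estimated correlation), and 3 passed adjusted over the list alone. Igfbp2 and Mgp, which the meninges list holds, rose by 0.87 ± 0.21 and 0.41 ± 0.10, and Pparg, the adipocyte regulator, fell by 0.48 ± 0.09 (adjusted p = 0.044, 0.0467 and 0.0116). The further largest rises were of Zfp385c, Rflna, Rbpjl, Alcam, Gsc, a homeobox gene, and Tac1, the substance P precursor gene, by 0.89 to 1.06. The largest falls were of Gal, the galanin gene (-1.16 ± 0.19, adjusted p = 0.00745), and Cldn10 (-1.08 ± 0.14, adjusted p = 0.0035), followed by Plac8, C2, Cytip, Rac2, Rassf4 and Pacsin1. For Pacsin1, 1 of the 2 other probes of the gene had the opposite sign.

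Blood and vessel groups were lower in A-KO:R-Het. Neutrophil genes had a median of -0.97 (adjusted p = 1.64e-09, adjusted p = 0.246 with an estimated correlation), with 0 members past the threshold and 10 adjusted over the list alone. B cell genes had a median of -0.33 (adjusted p = 0.00162, adjusted p = 0.323 with an estimated correlation), interferon response genes of -0.39 (adjusted p = 0.00264, adjusted p = 0.358 with an estimated correlation), and endothelial genes of -0.21 (adjusted p = 0.00148, adjusted p = 0.323 with an estimated correlation). Osteocyte genes stood at -0.22 (adjusted p = 0.0277, adjusted p = 0.203 with an estimated correlation), with Phex at -0.40 ± 0.13 and Dmp1 at -0.56 ± 0.20 (adjusted p = 0.145 and 0.182). Erythroid (-0.30, adjusted p = 0.0356), macrophage (-0.14, adjusted p = 0.0489) and mitochondrial respiration genes (-0.10, adjusted p = 0.0288) were lower; the calls were lost at adjusted p = 0.58, 0.58 and 0.586 with an estimated correlation. Skeletal muscle genes had a median of -1.20 beside them (adjusted p = 0.00148, adjusted p = 0.586 with an estimated correlation). The 14 called lists kept their sign on both chips, with cartilage medians of 0.70 and 1.07 and osteoclast medians of -0.48 and -0.41. With chip as a block 189 genes changed, chip 1 alone gave 0 and chip 2 alone gave 1. The count of 187 was 93 with the damaged array kept in, 5 without the 3 arrays highest in muscle genes, 90 and 80 without WT replicates 1 and 3, and 68 and 67 without A-KO:R-Het replicates 3 and 4. With 1 array left out, medians ran widely or calls were lost for osteocyte (-0.27 to -0.20, lost in 2), Wnt ligands and receptors (0.07 to 0.18), suture (0.11 to 0.20), erythroid (-0.53 to -0.11, lost in 4), neutrophil (-1.24 to -0.60), macrophage (-0.17 to -0.09, lost in 8), skeletal muscle (-1.70 to -0.51, lost in 2), interferon response (-0.55 to -0.19, lost in 1) and mitochondrial respiration (-0.17 to -0.03, lost in 3). Other settings that ended list calls or moved medians over 1.5 times gave, with the damaged array kept, erythroid (-0.30, adjusted p = 0.12), macrophage (-0.14, adjusted p = 0.137) and mitochondrial respiration (-0.10, adjusted p = 0.121). With the muscle covariate the values were skeletal muscle (0.04, adjusted p = 0.75) and mitochondrial respiration (-0.01, adjusted p = 0.525). Leaving out the 3 arrays highest in muscle genes gave osteocyte (-0.25, adjusted p = 0.0508), suture (0.11), macrophage (-0.26), B cell (-0.25, adjusted p = 0.0579), skeletal muscle (-0.01, adjusted p = 0.992), interferon response (-0.65) and mitochondrial respiration (0.01, adjusted p = 0.992). The macrophage call was lost with chip as a block (-0.14, adjusted p = 0.0535).

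Removing 1 Runx2 allele from mice without Axin2 raised cartilage genes. Matn1, a cartilage matrix protein, was 6.43-fold higher in A-KO:R-Het than in A-KO (2.69 ± 0.54, adjusted p = 0.0405, n = 4 and 3), and Ucma, a protein of growth plate cartilage, was 6.07-fold higher (2.60 ± 0.42, adjusted p = 0.0159). Col2a1, which encodes the main cartilage collagen, rose 4.43-fold (2.15 ± 0.43, adjusted p = 0.0394), and Col9a2 rose 4.45-fold (2.15 ± 0.42, adjusted p = 0.0376). In all, 55 genes changed, 35 higher and 20 lower, with 1072 at an unadjusted p under 0.05. For all 55 the arrays of both genotypes did not overlap, against 1135 such genes in all and 5.71% by chance.

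Of 15 measured cartilage genes, 10 rose, and 14 did when adjusted over the list alone. Their median was 1.19 (adjusted p = 4.24e-26, adjusted p = 0.0435 with an estimated correlation). Matn4 (1.05 ± 0.12, adjusted p = 0.00331), Epyc (1.44 ± 0.20, adjusted p = 0.00609) and Comp (1.30 ± 0.24, adjusted p = 0.0291) were among them, and Mia (1.98 ± 0.26, adjusted p = 0.00537) and Scrg1 (1.28 ± 0.22, adjusted p = 0.0265) rose outside the list. Zfp385c and Rbpjl rose by 1.23 ± 0.23 and 1.19 ± 0.21. Osteoclast genes were lower, with a median of -0.23 (adjusted p = 6.09e-06, adjusted p = 0.0549 with an estimated correlation); Oscar (-0.72 ± 0.14, adjusted p = 0.0394) and Tcirg1 (-0.46 ± 0.09, adjusted p = 0.0405) fell, and 5 members passed adjusted over the list alone. Osteoblast and bone matrix genes were lower, with a median of -0.18 over 19 genes (adjusted p = 0.00314, adjusted p = 0.408 with an estimated correlation). Ifitm5, a gene of mineralizing osteoblasts, was the 1 member that fell (-0.49 ± 0.10, adjusted p = 0.0473), and 4 passed adjusted over the list alone.

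Fibrous matrix genes were higher, with a median of 0.12 (adjusted p = 0.00275, adjusted p = 0.089 with an estimated correlation), and Fmod rose by 0.52 ± 0.11 (adjusted p = 0.0471). With the damaged A-KO array kept in, this median was -0.08. Rspo3, which amplifies Wnt signalling, rose by 0.53 ± 0.11 (adjusted p = 0.0435). B cell genes were higher than in A-KO, with a median of 0.46 (adjusted p = 0.000821, adjusted p = 0.408 with an estimated correlation), and Vpreb1 rose by 1.12 ± 0.20 (adjusted p = 0.0291). Brain and nerve genes (0.41, adjusted p = 0.00584, adjusted p = 0.107 with an estimated correlation), meninges genes (0.26, adjusted p = 0.00639, adjusted p = 0.0859 with an estimated correlation) and erythroid genes (0.39, adjusted p = 0.0104, adjusted p = 0.58 with an estimated correlation) were higher with 0 members past the threshold. Immediate early and handling stress genes (0.30, adjusted p = 0.0256) and mast cell genes (0.32, adjusted p = 0.046) were higher as well, and these calls were lost at adjusted p = 0.662 and 0.608 with an estimated correlation. Cell cycle (-0.15, adjusted p = 0.00275) and endothelial genes (-0.18, adjusted p = 0.0256) were lower, each at adjusted p = 0.585 with an estimated correlation.

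The largest falls against A-KO were of Asic3, an acid-sensing ion channel (-0.81 ± 0.12, adjusted p = 0.0113), and Ccn5 (-0.81 ± 0.17, adjusted p = 0.0454). Pacsin1, Guca1a, Dipk1c, Psat1, an enzyme of serine synthesis, Kcnj15, Gm266 and Atp6v1c1, a proton pump subunit, fell by 0.55 to 0.67. Cartilage medians were 1.09 and 1.28 on the 2 chips and osteoclast medians -0.45 and -0.21, and 10 of the 12 called lists had the same sign on both. The exceptions were brain and nerve genes, at -0.05 and 0.51, and immediate early genes, at 0.75 and -0.01. With chip as a block 53 genes changed, chip 1 alone, with 1 A-KO array, gave 0 and chip 2 alone gave 1. The count of 55 was 23 with the damaged array kept in, 9, 1 and 3 without A-KO replicates 1, 3 and 4, 26, 15 and 7 without A-KO:R-Het replicates 1, 3 and 4, 22 and 28 without WT replicates 1 and 4, and 28 and 85 without R-Het replicates 3 and 4. Leaving out single arrays moved these medians over 1.5 times or ended their calls: fibrous matrix (0.07 to 0.16), erythroid (0.16 to 0.52, lost in 3), mast cell (0.18 to 0.47, lost in 6), endothelium (-0.20 to -0.13, lost in 4), brain and nerve (0.25 to 0.48) and immediate early (0.04 to 0.49, lost in 3). List medians that lost their call or moved over 1.5 times in other settings were, with the damaged array kept, osteoblast (-0.32), fibrous matrix (-0.08, adjusted p = 0.193), erythroid (0.18, adjusted p = 0.15), B cell (0.22, adjusted p = 0.0942) and mast cell (0.15, adjusted p = 0.521). The endothelium call was lost with chip as a block (-0.17, adjusted p = 0.0665).

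Loss of Axin2 in Runx2 heterozygous mice, A-KO:R-Het against R-Het, changed 0 single genes in limma's test, whose smallest adjusted p was 0.183. At an unadjusted p under 0.05 there were 641 genes, and array weights and a robust variance trend also gave 0 past the threshold. The 641 became 1188 with array weights. With 1 array left out it ran from 415, without A-KO:R-Het replicate 3, to 1121, without A-KO:R-Het replicate 1. Abca5 had the smallest p and stood at 0.49 ± 0.08 (adjusted p = 0.183, n = 4 each). Slc9a3r1 (-0.51 ± 0.10), Nedd4l (-0.35 ± 0.07), Snx5 (0.94 ± 0.20) and Zic1 (0.63 ± 0.13) followed, each at an adjusted p of 0.437. Arrays of the 2 genotypes did not overlap for 275 genes, with 2.86% given by chance.

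Groups of blood cell genes were lower in this comparison. Neutrophil genes had a median of -0.68 (adjusted p = 2.01e-09, adjusted p = 0.547 with an estimated correlation), with 2 members adjusted over the list alone, and Camp, a granule peptide, stood at -1.33 ± 0.40 (adjusted p = 0.734). B cell genes had a median of -0.34 (adjusted p = 0.000355, adjusted p = 0.547 with an estimated correlation), with 2 members adjusted over the list alone. Immediate early and handling stress genes stood at -0.41 (adjusted p = 2.01e-05), interferon response genes at -0.24 (adjusted p = 0.00373) and erythroid genes at -0.37 (adjusted p = 0.014), and these calls were lost at adjusted p = 0.547, 0.614 and 0.614 with an estimated correlation. Cartilage genes were higher, with a median of 0.45 (adjusted p = 1.07e-05, adjusted p = 0.547 with an estimated correlation). Osteocyte genes (-0.15, adjusted p = 0.0177, adjusted p = 0.547 with an estimated correlation) and BMP and TGF-beta genes (-0.05, adjusted p = 0.0304, adjusted p = 0.614 with an estimated correlation) were lower. All 8 lists had 0 members past the threshold over all genes and the same sign on both chips, with cartilage medians of 0.26 and 0.68 and neutrophil medians of -1.09 and -0.41. Chip as a block and each chip alone also gave 0 genes, and 1 gene was called without A-KO:R-Het replicate 1. The 8 called lists were 5 without A-KO:R-Het replicate 3. With 1 array left out, medians ran widely or calls were lost for osteocyte (-0.26 to -0.13, lost in 2), BMP and TGF-beta (-0.09 to -0.03, lost in 6), cartilage (0.28 to 0.65), erythroid (-0.58 to -0.07, lost in 3), neutrophil (-0.98 to -0.38), B cell (-0.43 to -0.13, the latter without R-Het replicate 3), interferon response (-0.37 to -0.08, lost in 1) and immediate early (-0.61 to -0.24). Other settings that ended list calls or moved medians over 1.5 times gave, without the 3 arrays highest in muscle genes, osteocyte (-0.26), BMP and TGF-beta (-0.08), erythroid (-0.24) and interferon response (-0.08, adjusted p = 0.34).

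The interaction asked whether Axin2 loss acted differently with 1 and with both Runx2 alleles. No gene passed, at 0 in limma's test with a smallest adjusted p of 0.743, 0 with array weights, and 611 genes at an unadjusted p under 0.05. Vpreb1 (1.33 ± 0.28), Mzb1 (0.84 ± 0.19), Tnfrsf22 (-0.66 ± 0.14), Baalc (-0.54 ± 0.12) and Agpat2 (-0.54 ± 0.13) had the smallest p-values, each at an adjusted p of 0.743. As groups, cartilage genes had a positive interaction, with a median of 0.70 (adjusted p = 2.6e-09, adjusted p = 0.525 with an estimated correlation) and 3 members adjusted over the list alone. The median change of this list with Axin2 loss was -0.24 with both Runx2 alleles and 0.45 with 1. B cell genes also had a positive interaction (0.42, adjusted p = 0.00264, adjusted p = 0.525 with an estimated correlation), from -0.61 with both alleles and -0.34 with 1. Skeletal muscle genes had a median of 1.10 (adjusted p = 0.0221, adjusted p = 0.832 with an estimated correlation). The other 5 lists called were erythroid, macrophage, mast cell, cell cycle and unfolded protein response genes, with medians of 0.36, 0.20, 0.42, -0.19 and -0.13 (adjusted p = 0.047, 0.0221, 0.0222, 0.013 and 0.0328). Their calls were lost at adjusted p = 0.681, 0.658, 0.658, 0.681 and 0.525 with an estimated correlation. All 8 lists had the same sign on both chips, with cartilage medians of 0.69 and 0.73. Chip as a block and each chip alone gave 0 genes, and 1 gene was called without R-Het replicate 3. The 8 called lists were 3 with the damaged array kept, 4 with the muscle covariate, 3 without R-Het replicate 3, 4 without A-KO replicate 4, and 5 without WT replicate 1 or 3, R-Het replicate 1 or 2, or A-KO:R-Het replicate 1, 3 or 4. Leaving out single arrays moved these medians over 1.5 times or ended their calls: cell cycle (-0.27 to -0.10, lost in 4), erythroid (0.23 to 0.57, lost in 9), macrophage (0.14 to 0.27, lost in 5), mast cell (0.27 to 0.57, lost in 7), skeletal muscle (0.50 to 2.15, lost in 8) and unfolded protein response (-0.24 to -0.09, lost in 7). List medians that lost their call or moved over 1.5 times in other settings were, with the damaged array kept, erythroid (0.24, adjusted p = 0.364), B cell (0.25, adjusted p = 0.185), mast cell (0.19, adjusted p = 0.324), skeletal muscle (0.59, adjusted p = 0.185) and unfolded protein response (-0.09, adjusted p = 0.185). With the muscle covariate these were cell cycle (-0.15, adjusted p = 0.0657), mast cell (0.36, adjusted p = 0.0958), skeletal muscle (-0.01, adjusted p = 0.92) and unfolded protein response (-0.11, adjusted p = 0.117). Without the 3 arrays highest in muscle genes these were cell cycle (-0.12, adjusted p = 0.0674), erythroid (0.30, adjusted p = 0.0983), macrophage (0.37) and B cell (0.29, adjusted p = 0.273). The erythroid call was lost with chip as a block (0.39, adjusted p = 0.0532).

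Averaged over both Runx2 genotypes, B cell genes were lower as a group without Axin2 (camera adjusted p = 3.76e-09, adjusted p = 0.254 with an estimated correlation), and Abca5, Wnt10a, Notum, Hhip and Sqle rose. Mzb1 was 1.81-fold lower (-0.86 ± 0.10, adjusted p = 0.000689, 7 arrays without and 8 with Axin2), and Vpreb1 2-fold lower (adjusted p = 0.00494). Abca5 rose 1.53-fold (0.61 ± 0.06, adjusted p = 0.000242). Notum, a secreted Wnt inhibitor and Wnt target, rose 1.45-fold (0.54 ± 0.09, adjusted p = 0.0149), and Wnt10a rose 1.49-fold (0.57 ± 0.10, adjusted p = 0.0134). On the WT arrays Wnt10a read 6.56 to 6.72 and Abca5 6.32 to 6.61 (log2 intensity), and on the A-KO arrays Mzb1 read 6.39 to 6.68. These levels lie near the array median, which was the bound of the filter. The folds of these genes, here and above, thus start or end near that bound. In total 64 genes changed, 18 higher and 46 lower, with 1352 at an unadjusted p under 0.05.

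The B cell list had a median of -0.46 (adjusted p = 3.76e-09, adjusted p = 0.254 with an estimated correlation). Vpreb1, Vpreb3, Cd79b and Cd79a fell, by 0.60 to 1.00, and 6 of 8 members passed adjusted over the list alone. Fcrla, Mzb1 and Atp2a3 fell outside the list, and so did Prg2, the eosinophil major basic protein gene (-0.93 ± 0.18, adjusted p = 0.0307), Cytip, Nup210 and Plac8. Neutrophil genes had a median of -0.75 (adjusted p = 4e-12, adjusted p = 0.254 with an estimated correlation), with 0 members past the threshold and 12 of 14 adjusted over the list alone. Erythroid genes had a median of -0.52 (adjusted p = 3.99e-06, adjusted p = 0.254 with an estimated correlation), with 0 and 7 members. Mast cell (-0.43, adjusted p = 0.00225, adjusted p = 0.378 with an estimated correlation) and macrophage genes (-0.07, adjusted p = 0.0171, adjusted p = 0.516 with an estimated correlation) were lower as well. Interferon response genes had a median of -0.26 (adjusted p = 0.00168, adjusted p = 0.378 with an estimated correlation), and Gbp2, an interferon-induced GTPase, fell by 0.63 ± 0.13 (adjusted p = 0.0372). Immediate early and handling stress genes stood at -0.42 (adjusted p = 1.38e-06, adjusted p = 0.32 with an estimated correlation), with 0 members past the threshold and 5 adjusted over the list alone.

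Among 12 Wnt targets and feedback inhibitors, Notum was the 1 member that rose, and 2 passed adjusted over the list alone. Their median was 0.09 (adjusted p = 0.0213, adjusted p = 0.254 with an estimated correlation). Hhip rose by 0.50 ± 0.09 (adjusted p = 0.0146). Also higher were Sqle, the squalene epoxidase (0.73 ± 0.15, adjusted p = 0.035), Tmem97, a sterol-responsive membrane protein (0.40 ± 0.08, adjusted p = 0.0408), Scd1, a fatty acid desaturase (0.36 ± 0.07, adjusted p = 0.035), and Smpdl3b (0.49 ± 0.11, adjusted p = 0.0477). Adh7, an alcohol and retinol dehydrogenase, rose most (0.95 ± 0.18, adjusted p = 0.0253), and Ifitm5 rose by 0.36 ± 0.07 (adjusted p = 0.0282). Hs3st3a1, a heparan sulfate sulfotransferase, and Avil rose by 0.40 ± 0.08 and 0.40 ± 0.07. Cell cycle genes were higher (0.13, adjusted p = 0.00317, adjusted p = 0.622 with an estimated correlation) and osteocyte genes lower (-0.10, adjusted p = 0.0445, adjusted p = 0.254 with an estimated correlation), and neither list had a member past the threshold. The 10 called lists had the same sign on both chips, with B cell medians of -0.43 and -0.52. With chip as a block 55 genes changed, chip 1 alone gave 0 and chip 2 alone gave 3. The count of 64 was 2 with the damaged array kept in, 18 without the 3 arrays highest in muscle genes, 38 and 37 without WT replicates 1 and 3, 21 and 36 without A-KO replicates 1 and 4, 24 without A-KO:R-Het replicate 3, 34 and 32 without R-Het replicates 2 and 3, 104 without R-Het replicate 1, and 199 without A-KO:R-Het replicate 1. With 1 array left out, medians ran widely or calls were lost for osteocyte (-0.16 to -0.08, lost in 7), Wnt targets (0.06 to 0.14, lost in 3), macrophage (-0.12 to -0.06, lost in 4), mast cell (-0.53 to -0.25), interferon response (-0.41 to -0.15) and immediate early (-0.54 to -0.24). Other settings that ended list calls or moved medians over 1.5 times gave, with the damaged array kept, Wnt targets (0.08, adjusted p = 0.0872), neutrophil (-0.47), macrophage (-0.12) and mast cell (-0.28). Leaving out the 3 arrays highest in muscle genes gave osteocyte (-0.21), Wnt targets (0.09, adjusted p = 0.0911), cell cycle (0.10, adjusted p = 0.0536) and mast cell (-0.15, adjusted p = 0.116). The osteocyte call was lost with chip as a block (-0.09, adjusted p = 0.0587).

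**Figure D3:**
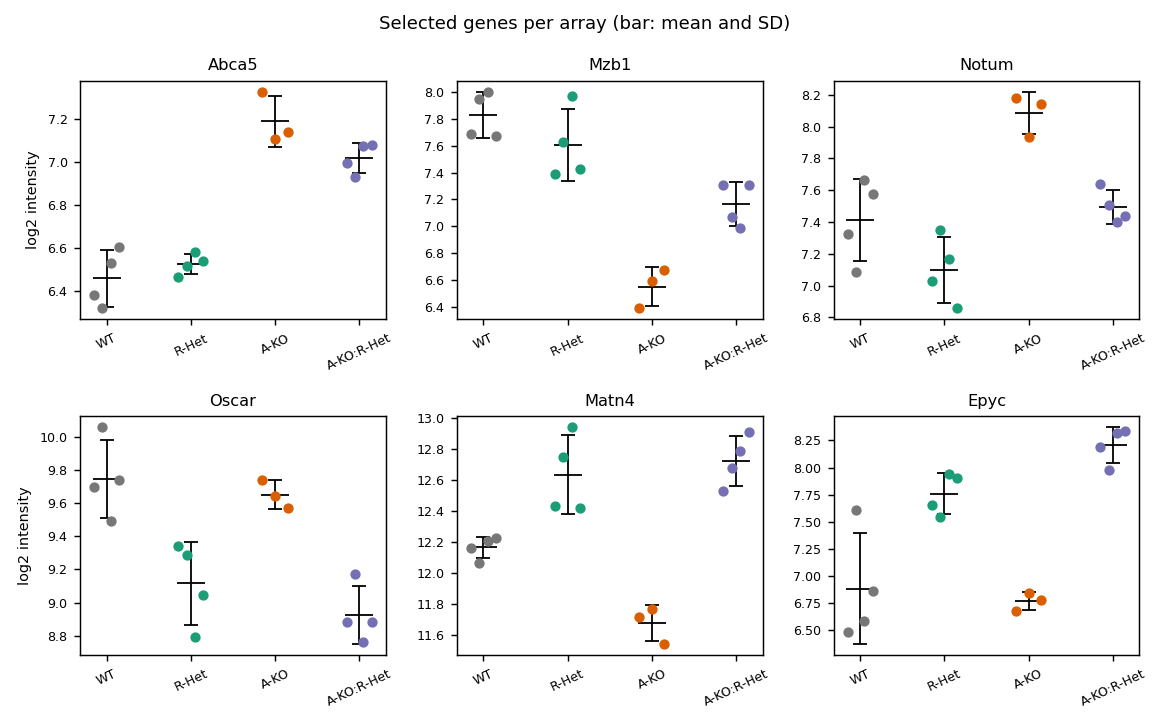
Points give log2 intensity of Abca5, Mzb1, Notum, Oscar, Matn4 and Epyc on each of the 15 arrays by genotype, with bars for the group mean and SD. Abca5 was higher and Mzb1 lower in both groups without Axin2, and Oscar was lower and Matn4 higher in both groups with 1 Runx2 allele.

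Averaged over both Axin2 genotypes, cartilage and fibrous matrix genes were higher and osteoclast genes lower with loss of 1 Runx2 allele. Epyc rose 2.23-fold (1.16 ± 0.14, adjusted p = 0.00147, 8 arrays with 1 and 7 with both Runx2 alleles), Matn4 rose 1.69-fold (0.76 ± 0.09, adjusted p = 0.00147) and Matn1 rose 3.52-fold (1.81 ± 0.37, adjusted p = 0.02). Tcirg1 was 1.38-fold lower (-0.47 ± 0.06, adjusted p = 0.00196) and Oscar 1.60-fold lower (-0.68 ± 0.10, adjusted p = 0.00362). In total 162 genes changed, 89 higher and 73 lower, with 1249 at an unadjusted p under 0.05.

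Of the 15 cartilage genes, 11 rose, and all 15 passed adjusted over the list alone. Their median was 0.89 (adjusted p = 7.26e-24, adjusted p = 0.02 with an estimated correlation), and Ucma, Col2a1, Col9a2, Acan and Comp rose by 0.89 to 1.61. Mia rose by 1.40 ± 0.18 (adjusted p = 0.00147), and Meltf, Rbpjl and Zfp385c rose by 1.23 ± 0.26, 0.94 ± 0.14 and 0.91 ± 0.16. Osteoclast genes had a median of -0.25 (adjusted p = 1.68e-08, adjusted p = 0.0166 with an estimated correlation), and Tcirg1, Oscar, Dcstamp (-0.56 ± 0.10) and Acp5 (-0.46 ± 0.09) fell, with 6 of 13 passing adjusted over the list alone. Fibrous matrix genes had a median of 0.16 (adjusted p = 1.68e-08, adjusted p = 0.00845 with an estimated correlation), and Fmod (0.50 ± 0.08), Dpt (0.68 ± 0.13) and Ogn (0.33 ± 0.07) rose, with 9 of 20 adjusted over the list alone. These 3 lists were the calls of this comparison that held with an estimated correlation. In the single comparisons, 2 such calls held for R-Het against WT, 2 for A-KO:R-Het against WT, 1 for A-KO:R-Het against A-KO and 0 otherwise.

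Ifitm5 fell by 0.38 ± 0.07 (adjusted p = 0.0111), the 1 member past the threshold among 19 osteoblast and bone matrix genes, whose median was -0.09 (adjusted p = 0.0135, adjusted p = 0.489 with an estimated correlation). Notum fell by 0.45 ± 0.09 (adjusted p = 0.0212), although Wnt targets as a list were not called. Rspo3 rose by 0.31 ± 0.07 and Six2 by 0.37 ± 0.06 (adjusted p = 0.0432 and 0.0079), each the 1 member past the threshold of its list; Wnt ligands, receptors and antagonists had a median of 0.05 (adjusted p = 0.0401, adjusted p = 0.372 with an estimated correlation) and suture genes of 0.07 (adjusted p = 0.0174, adjusted p = 0.372 with an estimated correlation). Foxd1, a meningeal transcription factor, rose by 0.38 ± 0.08, and Pmp22, a myelin protein, by 0.35 ± 0.08 (adjusted p = 0.03 and 0.045); the meninges list stood at 0.16 (adjusted p = 0.0135, adjusted p = 0.0974 with an estimated correlation) and the brain and nerve list at 0.31 (adjusted p = 0.0138, adjusted p = 0.18 with an estimated correlation). The largest falls were of Gal (-0.77 ± 0.14, adjusted p = 0.00891), Hapln4, Ccn5, Cdkn2b, a cyclin-dependent kinase inhibitor, Cldn10, Arsb, a lysosomal sulfatase, Pacsin1 and Manba (-0.52 ± 0.06, adjusted p = 0.00147).

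Endothelial genes (-0.17, adjusted p = 0.00172), mitochondrial respiration genes (-0.10, adjusted p = 0.0135) and cell cycle genes (-0.07, adjusted p = 0.0497) were lower, and their calls were lost at adjusted p = 0.372, 0.626 and 0.687 with an estimated correlation. Immediate early and handling stress genes (0.27, adjusted p = 0.00614) and B cell genes (0.21, adjusted p = 0.0268) were higher, each at adjusted p = 0.626 with an estimated correlation. Skeletal muscle genes had a median of -0.76 beside them (adjusted p = 0.0196, adjusted p = 0.73 with an estimated correlation). All 14 lists had the same sign on both chips, with cartilage medians of 0.77 and 1.00, osteoclast medians of -0.15 and -0.26, and fibrous medians of 0.17 and 0.17. With chip as a block 169 genes changed, chip 1 alone gave 2 and chip 2 alone gave 1. The count of 162 was 92 and 83 without A-KO replicates 3 and 4, 103 without A-KO:R-Het replicate 4, 100 without R-Het replicate 3 and 244 without R-Het replicate 4. The 14 called lists were 8 without A-KO replicate 1. Leaving out single arrays moved these medians over 1.5 times or ended their calls: osteoblast (-0.14 to -0.04, lost in 2), Wnt ligands and receptors (0.01 to 0.07, lost in 7), suture (0.06 to 0.11, lost in 1), cell cycle (-0.11 to -0.03, lost in 7), B cell (0.15 to 0.29, lost in 4), skeletal muscle (-1.19 to -0.39, lost in 6), brain and nerve (0.22 to 0.37, lost in 1), meninges (0.14 to 0.27), immediate early (0.09 to 0.38, lost in 1) and mitochondrial respiration (-0.14 to -0.06, lost in 3). List medians that lost their call or moved over 1.5 times in other settings were, with the damaged array kept, osteoblast (-0.14), suture (0.11), fibrous matrix (0.10), B cell (0.12, adjusted p = 0.368), meninges (0.10) and mitochondrial respiration (-0.20). With the muscle covariate these were Wnt ligands and receptors (0.06, adjusted p = 0.0539), suture (0.07, adjusted p = 0.0539), B cell (0.19, adjusted p = 0.0528), skeletal muscle (-0.01, adjusted p = 0.973) and mitochondrial respiration (-0.06, adjusted p = 0.154). Without the 3 arrays highest in muscle genes these were osteoblast (-0.04, adjusted p = 0.254), Wnt ligands and receptors (0.03, adjusted p = 0.0519), cell cycle (-0.12, adjusted p = 0.0665), B cell (0.34), brain and nerve (0.15, adjusted p = 0.069) and meninges (0.17, adjusted p = 0.0538).

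The effects of each gene in the 2 backgrounds of the other gene were set against each other in pairs that share no arrays. Across 9918 genes, the Axin2 effect with both Runx2 alleles correlated with that with 1 at a Pearson r of 0.36 and a Spearman rho of 0.246. In 100 relabellings of the arrays, r ran from -0.48 to 0.47. Without R-Het replicate 4 it was 0.191. For the Runx2 effect in mice with and without Axin2, r was 0.32 and rho 0.215, and relabelling gave -0.54 to 0.46. Genes are not independent replicates, so the relabellings and not the number of genes set the scale.

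The 10 lists not yet named were called in no comparison, and their smallest adjusted p over the 8 comparisons follows. It was 0.135 for FGF signalling and for proteoglycan chain synthesis, both in R-Het against WT, 0.147 for ribosomal proteins, 0.156 for hedgehog signalling, 0.291 for adipocyte genes, 0.303 for skin and hair, 0.361 for smooth muscle and pericyte, 0.449 for matrix metalloproteinases, 0.604 for the beta-catenin destruction complex and 0.683 for hypoxia and glycolysis. The T and NK cell list had 2 measured members and was not tested.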

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

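The tests with the skeletal muscle covariate, of a larger share of cartilage, of less blood and marrow, and of chromosome segments beside the Axin2 and Runx2 genes were chosen after the data had been seen, while those of chip, of other splits and of the interaction were planned.

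Cartilage genes were higher with loss of a Runx2 allele, at a median of 0.89. Skeletal muscle carried over with the bone is argued against as the whole cause, because the median was 0.761 with the muscle list mean as a covariate (camera adjusted p = 8.78e-25). Chip is argued against mainly by the design, which put every genotype on both chips. The smaller of the medians on each chip alone was 0.769. A larger share of cartilage in the tissue taken stays open: the list's genes correlated between arrays of 1 genotype at a mean of 0.462, where the highest of 1000 random lists matched on level reached 0.158, but genes switched on together would correlate too. Higher expression within the cells of R-Het and A-KO:R-Het calvaria was not tested and cannot be told apart from it.

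B cell genes were lower with Axin2 loss, at a median of -0.46, a call lost at adjusted p = 0.254 with an estimated correlation. The tables argue against skeletal muscle, with a median of -0.475 when the muscle list mean was a covariate. Chip is argued against mainly by the design, with every genotype on both chips, and the smaller of the medians on each chip alone was -0.432. Less blood and marrow in the tissue taken stays open: the mean change was -0.528 ± 0.108 for B cell, -0.774 ± 0.253 for neutrophil and -0.648 ± 0.199 for erythroid genes, and the B cell change differed from the mean of the other 2 by 0.183 ± 0.227. Within genotypes the B cell list mean correlated with the neutrophil one at 0.06 and the erythroid one at 0.119 (permutation p = 0.374 and 0.304). In A-KO:R-Het replicate 2 the lists parted, with the neutrophil mean the lowest of its genotype (B cell -0.084, neutrophil -1.405). In A-KO replicate 4 both means were the highest of their genotype (-0.441 and 0.074). With 15 arrays, less blood and marrow in the tissue cannot be told apart from an effect of Axin2 loss on marrow cells themselves, which was not tested.

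Of the 100 tested genes nearest to Axin2, 3 changed with its loss (Abca5, Cd79b and Slc9a3r1, with 9, 16 and 23 tested genes between), against 61 of 9814 others (Fisher's exact test, one-sided p = 0.0266). In A-KO against WT the same 3 changed, against 28 of 9814 others (exact p = 0.00365), and with the B cell list left out p was 0.121 for the averaged effect and 0.0295 for A-KO against WT. A chromosome segment of another strain carried along with the targeted allele could bring this about. It cannot be told apart from a response to Axin2 loss because strain variants were not examined. Chip is argued against mainly by the design, with every genotype on both chips, and 100% of these calls stayed with chip as a block. Beside Runx2, 2 of the 100 nearest genes changed with loss of its allele (Klc4 and Guca1a), against 160 of 9815 others (exact p = 0.489), which decides nothing.

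For the 4 counts over 0 between single genotypes and for both averaged effects, the real labels gave the most genes. The share reached was under 1 in 20, but it was the smallest that 35 splits or 100 relabellings could give. It was not adjusted over the tests made, so it argues against chance without excluding it. For R-Het against WT the margin was small, and its count was 0 with every probe on its own. The real count and the highest of all other splits were 31 and 2 for A-KO against WT, 5 and 2 for R-Het against WT, 187 and 4 for A-KO:R-Het against WT, and 55 and 17 for A-KO:R-Het against A-KO, each reached in 1 of 35 splits. In 100 drawn relabellings they were 64 and 43 for Axin2 loss averaged and 162 and 42 for Runx2 allele loss averaged, each reached in 1. With 0 genes in A-KO:R-Het against R-Het and in the interaction, all 35 splits and all 100 relabellings give as many by construction, which decides nothing. The highest gave 224 and 40. The split with 224, R-Het replicates 1 to 3 with A-KO:R-Het replicate 1 against the rest, points to a structure of the samples, which was not tested. On its first side, immediate early list means were 0.273 to 0.505 and scores on the second principal component 5.37 to 11.9, against -0.559 to 0.06 and -13.11 to 2.89 on the other. The agreement of the Axin2 effects, r = 0.36, was reached in 4 of 100 relabellings, with a highest of 0.472. That share lies under 1 in 20, but 100 draws are too few to place it there with certainty, so chance is not excluded. Without R-Het replicate 4 the r of the Axin2 effects was 0.191, for which no relabellings were run. The agreement of the Runx2 effects, r = 0.315, was reached in 7 with a highest of 0.46, so chance cannot be excluded. By Spearman rho, 0.246 for the Axin2 effects was reached in 1 of 100 relabellings and 0.215 for the Runx2 effects in 3. For the Runx2 effects the 2 measures thus fall on different sides of 1 in 20.

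The effect of Axin2 loss differed between Runx2 backgrounds, by the test of the interaction, for 8 lists. This number was 3 with the damaged array kept, 4 with the muscle covariate, 3 without R-Het replicate 3, 4 without A-KO replicate 4, and 5 without WT replicate 1 or 3, R-Het replicate 1 or 2, or A-KO:R-Het replicate 1, 3 or 4. The median differences were 0.698 for cartilage, -0.19 for cell cycle, 0.36 for erythroid, 0.2 for macrophage, 0.421 for B cell, 0.418 for mast cell, 1.102 for skeletal muscle and -0.127 for unfolded protein response genes, and none kept its call with an estimated correlation.

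Some values lay far from the other 3 of their genotype, and chance flags about 1 in 20 groups. Of 423 groups of 4 arrays tested, 25 were picked out (5.91%, against 5% by chance). The value and the others are given for each in log2, and the gap as a share of the group's range. Among lists, the arrays apart were A-KO:R-Het replicate 3 for osteocyte genes (-0.26, others -0.10 to -0.06, gap 0.839), R-Het replicate 4 for craniosynostosis and suture genes (-0.14, others 0.05 to 0.09, gap 0.839) and A-KO:R-Het replicate 1 for fibrous matrix and periosteum genes (0.04, others 0.11 to 0.12, gap 0.847). A-KO:R-Het replicate 1 stood apart for Dnajc17 (6.50, others 6.88 to 6.92, gap 0.916), Cd79b (7.55, others 7.18 to 7.22, gap 0.898) and Manba (9.32, others 8.99 to 9.04, gap 0.843). A-KO:R-Het replicate 2 stood apart for Ifitm5 (12.15, others 11.88 to 11.90, gap 0.923) and Baalc (6.98, others 6.92 to 6.93, gap 0.844). A-KO:R-Het replicate 3 stood apart for Dmp1 (7.52, others 7.85 to 7.89, gap 0.890), Pparg (7.13, others 6.99 to 7.01, gap 0.861) and Hs3st3a1 (9.46, others 9.12 to 9.18, gap 0.830). A-KO:R-Het replicate 4 stood apart for Axin2 (7.74, others 7.39 to 7.44, gap 0.862) and Fmod (11.11, others 10.81 to 10.83, gap 0.940).

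At the same chance rate of 1 in 20, single R-Het and WT arrays lay far from their others for further genes. R-Het replicate 1 stood apart for Cyp51 (8.40, others 7.65 to 7.77, gap 0.839). R-Het replicate 2 stood apart for Scrg1 (6.89, others 7.22 to 7.29, gap 0.833). R-Het replicate 3 stood apart for Cd79a (7.87, others 7.08 to 7.20, gap 0.848), Gbp2 (8.37, others 9.03 to 9.11, gap 0.887) and Kcnj15 (6.71, others 6.98 to 7.02, gap 0.871). R-Het replicate 4 stood apart for Cytl1 (6.69, others 6.51 to 6.54, gap 0.844). WT replicate 1 stood apart for Cldn10 (9.12, others 8.59 to 8.66, gap 0.869), Manba (9.89, others 9.69 to 9.72, gap 0.869) and Wnt10a (6.72, others 6.56 to 6.56, gap 0.982). WT replicate 2 stood apart for Dipk1c (6.61, others 6.75 to 6.77, gap 0.869). WT replicate 3 stood apart for Lss (6.59, others 6.74 to 6.76, gap 0.869) and Cd79a (7.54, others 7.23 to 7.27, gap 0.880).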

How the results depend on the processing

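The scaling to a common median, cyclic loess, the stricter filter, the skeletal muscle covariate and leaving out the 3 arrays highest in skeletal muscle genes were chosen after the data had been seen. Counts are given in the order A-KO, R-Het and A-KO:R-Het against WT, A-KO:R-Het against A-KO, Axin2 loss averaged and Runx2 allele loss averaged, where they were 31, 5, 187, 55, 64 and 162. They were 0, 0, 0, 0, 0 and 2 on chip 1 alone and 0, 0, 1, 1, 3 and 1 on chip 2 alone, where fewer arrays were compared. With the damaged array kept they were 0, 2, 93, 23, 2 and 115, and with array weights 119, 17, 351, 163, 218 and 326. Neither cause was tested. A threshold of 0.1 gave 120, 9, 339, 104, 178 and 304 by construction. Without the 3 arrays highest in skeletal muscle genes they were 6, 1, 5, 49, 18 and 128, and 1 for A-KO:R-Het against R-Het, from fewer arrays. The compared genotypes alone, fitted on fewer arrays, gave 60, 1, 122 and 21 for the first 4, and the cause was not tested. For A-KO against WT, chip as a random block gave 19, a robust variance trend 58 and median scaling 19. For R-Het against WT, every probe on its own gave 0, chip as a fixed block 9, the stricter filter 8 and the muscle covariate 1; the cause was not tested for any of these. Other background correction, quantile normalization, cyclic loess and no filter left every count within 1.5 times. Leaving out 1 array gave 4 to 76, 0 to 15, 67 to 225, 1 to 85, 21 to 199 and 83 to 244, and 0 to 1 for A-KO:R-Het against R-Het and for the interaction.

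Lists called in the 8 comparisons, in the order of the report, numbered 11, 10, 14, 12, 8, 8, 10 and 14. With an estimated correlation they were 0, 2, 2, 1, 0, 0, 0 and 3. With fry they were 1, 2, 8, 5, 0, 0, 1 and 5, and with 1 array left out 9 to 12, 4 to 13, 11 to 15, 8 to 12, 5 to 11, 3 to 11, 7 to 13 and 8 to 14. Of 1914 recomputed list results, mostly with 1 array left out, 1548 kept direction and call, 358 kept direction alone and 8 reversed. The cause was not tested. The skeletal muscle median became 0.077, 0.046 and 0.035 in A-KO, R-Het and A-KO:R-Het against WT and -0.011 in the interaction with the muscle covariate, which takes out that list by construction. Without the 3 arrays highest in skeletal muscle genes it was 0.194 in A-KO against WT, and the mitochondrial median in A-KO:R-Het against WT was 0.009. The fibrous matrix median in A-KO:R-Het against A-KO was -0.081 with the damaged array kept. Without A-KO replicate 1 the test of immediate early genes there turned its direction while their median stayed positive at 0.042, in a range of 0.042 to 0.486 with 1 array left out.

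The log2 fold changes of named genes past the threshold, 142 results, were recomputed 3918 times: 2827 kept direction and call, 1091 kept direction alone and 0 reversed. The rule named the largest changes and the smallest p-values, which seldom reverse. Genes past the threshold that the rule did not name were not recomputed one by one. Of 5694 recomputed values for named genes not past the threshold, 5616 kept direction and stayed, 69 passed and 9 changed direction. The agreement of effects ran from 0.191 to 0.44 for Axin2 loss and from 0.229 to 0.378 for Runx2 allele loss with 1 array left out. It was 0.305 and 0.27 without the filter, 0.349 and 0.3 with chip as a block, and 0.287 and 0.353 with the damaged array kept. No paired analysis was possible because the labels give no replicate numbers. Background correction from negative controls, its pairings with cyclic loess and median scaling, and the filter on detection p were not run, because the scanner table could not be joined to the samples. Depth on arrays is the signal over background, which is not given in the sources used here, and genes dimmer than the filter were not compared.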

Other observations

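The test of sterol synthesis genes was chosen after Sqle, Lss and Tmem97 had been seen among the genes changed with Axin2 loss, and the values of the damaged array were looked up after the comparisons.

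Values of sterol synthesis genes were compared without and with Axin2. In a list of 23 that leaves out Sqle, Lss and Tmem97, 16 genes were measured, 14 of them with a value over 0 and 0 past the threshold, with a median of 0.26 for Axin2 loss averaged. Fdps, which makes farnesyl diphosphate, stood at 0.79 ± 0.18, Cyp51, the lanosterol demethylase, at 0.47 ± 0.12, and Hmgcs1, an early enzyme of the mevalonate pathway, at 0.42 ± 0.10 (limma adjusted p = 0.0565, 0.0793 and 0.0713). The hypothesis that Axin2 loss raises this pathway stays open. With an estimated correlation the set test gave p = 0.0268, under the bound of 0.05 set for it, but adjusted p = 0.218 over 34 lists, and genes regulated together with those that raised the question are not independent evidence. In A-KO against WT the median was 0.35 (adjusted p = 0.385 with an estimated correlation) and in A-KO:R-Het against R-Het 0.21 (adjusted p = 0.575 with an estimated correlation). The median was 0.25 with the skeletal muscle covariate, 0.20 and 0.34 on chips 1 and 2, 0.21 with the damaged array kept, and 0.22 to 0.28 with 1 array left out.

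The damaged A-KO array was in no comparison. Of the 31 genes changed in A-KO against WT, 21 lay nearer to the WT mean than to the A-KO mean on it. Whether its genotype label is right was not tested, so the counts with this array kept rest on that label. Its log2 intensity was 6.67 for Abca5 (7.11 to 7.33 on the other A-KO arrays, 6.32 to 6.61 in WT), 8.1 for Mzb1 (6.39 to 6.68, 7.67 to 8), 7.61 for Slc9a3r1 (7.16 to 7.33, 7.78 to 8.04), 7.27 for Notum (7.93 to 8.18, 7.09 to 7.66), 12.84 for Matn4 (11.55 to 11.77, 12.07 to 12.23) and 7.3 for Axin2 (7.26 to 7.67, 7.42 to 7.88).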
